A study of Homo sapiens with 5 samples.

How the data were processed

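Expression was measured in 5 clones of human CD8+ T cells specific for melanoma, 3 from parental cells with a high IL-2:IFN index and 2 from parental cells with a low index. Per the labels' protocols, total RNA was isolated from the resting clones with a column kit, checked on a Bioanalyzer, reverse transcribed and labelled with biotin for an Affymetrix 3′ expression array, 1 array per clone. The deposited values are log2 expression per probe set. Per the submitters' processing notes, RMA (a background correction, normalization and summary of probes) and Partek were used; their versions, and the settings of the background correction and normalization, are not given in the sources used here. The values were used as deposited, with no further scaling. The means of the 5 arrays, 5.38 to 5.43, and the maxima, 14.24 to 14.43, lie in the range usual for RMA on the log2 scale. No probe intensities, detection calls or array batches were used here, and the number of arrays limits the precision.

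Genes were named through the platform annotation given with the data. Of 54675 probe sets, 41097 had 1 gene symbol, 1801 had several and 11777 were unnamed here, among which are 62 control probe sets. Of the probe sets with 1 symbol, 41043 matched the RefSeq gene table of assembly GRCh38.p14 by Entrez ID, and 0 symbols needed an update. Before any value was used, 212 probe sets were left out: 87 of sex-linked genes, 72 of rearranging antigen receptor genes and 53 of genes whose signal can follow an inherited allele. The 40885 probe sets left stood for 19673 genes, and each gene was given by the probe set with the highest mean over the 5 arrays. Genes with a mean under the 40th percentile of the gene means (5.09 on the log2 scale) counted as dim and were not tested, which left 11804 tested and 7869 dim genes. Signals of probe sets that can bind related transcripts (those marked _x_at or _s_at by the manufacturer) cannot be split between them. No coordinates are printed because no genome build is named with the values.

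High-index and low-index clones were compared with limma 3.58.1 in R 4.3.3: lmFit on the 5 arrays with the group as the only term, eBayes with a mean trend, two-sided tests and Benjamini-Hochberg adjustment, with genes called at an adjusted p under 0.05. The residual degrees of freedom were 3 and the prior degrees of freedom 1.66. The genes at an unadjusted p under 0.01 with at least a 2-fold difference were counted as a description, with no correction. Single measures of array quality were compared with two-sided exact permutation tests, whose smallest p for 3 against 2 is 0.2. Similarity was given as Pearson correlations between arrays across tested genes and as principal components, without a test.

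The test, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined. The 26 lists were memory, cytotoxic granule, effector differentiation, NK receptor, inhibitory receptor, costimulatory receptor, type 1 cytokine, type 2 and type 17 cytokine, common gamma chain cytokine signalling, chemokine receptor and homing, CD8 T cell identity, MHC class II presentation, cell cycle, apoptosis regulation, Wnt and Notch, interferon response, glycolysis, mitochondrial respiration, cholesterol synthesis, unfolded protein and heat shock response, immediate early response, and, as markers of other cells, B cell, monocyte and myeloid, CD4 helper and regulatory T cell, melanocyte and melanoma, and erythroid and platelet. They named 524 distinct genes, of which 479 were measured; the rest are not analysed here. Some genes are in more than 1 list. Lists with at least 5 tested members, 25 of them, were tested with limma's camera at its preset correlation of 0.01 and adjusted over the lists. Camera with a correlation estimated from the data and fry were run beside it. For each list the limma p-values of its members were also adjusted over the list alone, with no correction for the number of lists.

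The rule for named genes took, in each direction, 12 genes past the threshold by size of difference, and filled empty places with the genes of smallest limma p among those with at least a 2-fold difference and no overlap between the groups; since no gene passed, all 24 places were filled that way. It added up to 4 members per list, past the threshold first and then by smallest p, and 16 genes fixed by name for their part in memory and effector cells, of which 14 were measured and the others are not analysed here. Not every list member the rule allows is named. 

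The scripts were tested on simulated data for this comparison over 11804 genes, with the spread between clones as estimated here and 200 genes changed. The share of changed genes recovered was 4.1% at 2-fold, 36.2% at 4-fold, 54.2% at 8-fold and 78% at 16-fold, with 5 unchanged genes called. With no gene changed, 0 genes and 0 lists were called, and a list shifted on purpose was recovered, both at camera's preset correlation. The simulated noise was drawn for each gene on its own. The simulation therefore cannot show how often lists whose members move together are called wrongly. Camera with an estimated correlation and fry were not run on simulated data.

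The alternatives were eBayes without a trend and with a robust prior, array weights, no filter and a filter at the 60th percentile, the mean of a gene's probe sets and the probe set of largest variance, quantile normalization and median centring of the arrays, the clone number of the labels as a block, each clone left out in turn, an adjusted p under 0.1, ordinary least squares without moderation, and a fold of at least 1.5. Chosen after seeing the data, camera was also run with the estimated correlation under each other alternative. The labels number the clones within each group, and the patients are independent within each group. Whether same-numbered clones of the groups share a patient is not given in the sources used here, so the number was not treated as a pairing in the comparison reported.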

Results

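Gene expression was measured in 5 clones of human CD8+ T cells that recognise melanoma, on 1 Affymetrix 3′ expression array per clone. Each clone was grown from parental cells classed by an IL-2:IFN index, which sets interleukin-2 against interferon, and RNA was taken while the clones were resting. The high-index group held 3 clones from 3 independent patients, and the low-index group held 2 clones from 2 independent patients. Each array gave log2 expression values for 54675 probe sets, which stood for 19673 named genes, and the mean over all probe sets lay between 5.38 and 5.43 in the 5 arrays. The number of arrays limits the precision: the median 95% confidence interval of a difference between the groups reached 0.776 log2 units to either side. The comparison asked whether the resting expression of clones from high-index precursors differed from that of clones from low-index precursors. P-values measure the spread between clones, whose patients are independent within each group; whether a patient gave clones to both groups is not given in the sources used here. All differences are given as high-index minus low-index.

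The 5 clones did not sort by index group in their expression across the 11804 tested genes. Low-index clone 2 stood apart from the other 4 clones, with Pearson correlations across genes of 0.840 to 0.900 to them, whereas the other 4 clones correlated with each other at 0.945 to 0.978. Low-index clone 1 correlated at 0.978 with high-index clone 3 and at 0.861 with low-index clone 2, the other member of its group. Of the tested genes, 29.0% differed at least 2-fold between the low-index clones, and 2.55% did so between low-index clone 1 and high-index clone 3. The first principal component held 66.1% of the variance and placed low-index clone 2 away from the rest, while the second held 17.2% and placed high-index clone 2 away from the rest. Low-index clone 2 had the lowest value of the 5 clones for 5640 genes. Genes are not independent replicates, so these correlations describe the arrays and carry no test. No arrays were copies of each other: identical values made up 9.8% to 18.1% of the probe sets in each pair of arrays.

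The widest difference among the genes singled out by p was that of PAX8-AS1, a long non-coding RNA antisense to the transcription factor gene PAX8. Its log2 value was 8.73 ± 0.73 (SD, n = 3) in high-index and 4.38 ± 0.08 (SD, n = 2) in low-index clones, a difference of 4.36 (SE 0.47) or 20.5-fold. CRTAM, an adhesion receptor of activated CD8+ T cells and NK cells, had a mean 7.18-fold higher in high-index clones (7.36 ± 0.76, SD, n = 3, against 4.51 ± 0.19, SD, n = 2). AIF1, a calcium-binding protein that bundles actin, had a mean 6.62-fold higher (10.41 ± 0.64, SD, n = 3, against 7.68 ± 0.33, SD, n = 2), and the cytokine gene IL5 had a mean 3.06-fold higher (7.04 ± 0.06, SD, n = 3, against 5.43 ± 0.83, SD, n = 2). In the other direction, NID2, which encodes the basement membrane protein nidogen-2, had a mean 3.14-fold lower in high-index clones (4.71 ± 0.33, SD, n = 3, against 6.36 ± 0.31, SD, n = 2). None of these genes passed the test. Limma called 0 of the 11804 tested genes at a Benjamini-Hochberg adjusted p under 0.05, and the smallest adjusted p was 0.771. These 5 genes shared that value with many others, among them SOX10, whose unadjusted limma p was 0.362.

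Among the other genes chosen for a higher level in high-index clones, the log2 differences ran from 1.20 for ZSCAN5A, a zinc finger gene, to 3.24 for B3GNT5, an enzyme of glycosphingolipid synthesis. They included GSTM3, a glutathione S-transferase, at 2.72 (SE 0.31), CD84, a receptor of the SLAM family on lymphocytes, at 2.17 (SE 0.51), AGMAT, of the agmatinase family, at 2.07 (SE 0.49), MAFF, a small Maf transcription factor, at 1.59 (SE 0.37), ANKEF1 at 1.52 (SE 0.29), and ATL3, a GTPase that shapes the endoplasmic reticulum, at 1.32 (SE 0.19). All 8 probe sets of CD84 and all 3 of PAX8-AS1 had the higher mean in high-index clones, as against 1 of 2 for GSTM3, 2 of 3 for B3GNT5 and 3 of 4 for AIF1. The low-index levels of PAX8-AS1, GSTM3, ZSCAN5A, CRTAM, ANKEF1 and B3GNT5 lay below 5.09, the level under which a gene's mean counted as dim, so folds against them are less certain than the spread shows. The same holds for the high-index levels of NID2, DMRT2, DYNC2H1 and LYZ, which had the lower mean in high-index clones.

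Among the genes chosen for a lower level in high-index clones, DMRT2, a transcription factor of the DM domain family, had a difference of -2.46 (SE 0.80), with a high-index level below 5.09. UCHL1, a ubiquitin hydrolase, differed by -1.58 (SE 0.54), ZDHHC14, a palmitoyltransferase, by -1.49 (SE 0.57), DYNC2H1, a dynein of intraflagellar transport, by -1.36 (SE 0.49), and TMC4, a transmembrane channel-like gene, by -1.33 (SE 0.46). PINLYP, DTX3 (a ubiquitin ligase of the deltex family), CHRM3-AS2 (an antisense RNA), ITM2A (a membrane protein of T cells and other cells), LYZ (lysozyme) and SGSH (a lysosomal sulfatase) followed, at -1.18, -1.17, -1.05, -1.04, -1.02 and -1.01. Of the probe sets, 2 of 5 for DTX3 and 2 of 3 for DYNC2H1 had the direction given, and all of those for the other genes of this paragraph did. ITM2A was the most abundant of these genes, at 10.43 ± 0.43 (SD, n = 3) in high-index and 11.47 ± 0.34 (SD, n = 2) in low-index clones.

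**Figure D1:**
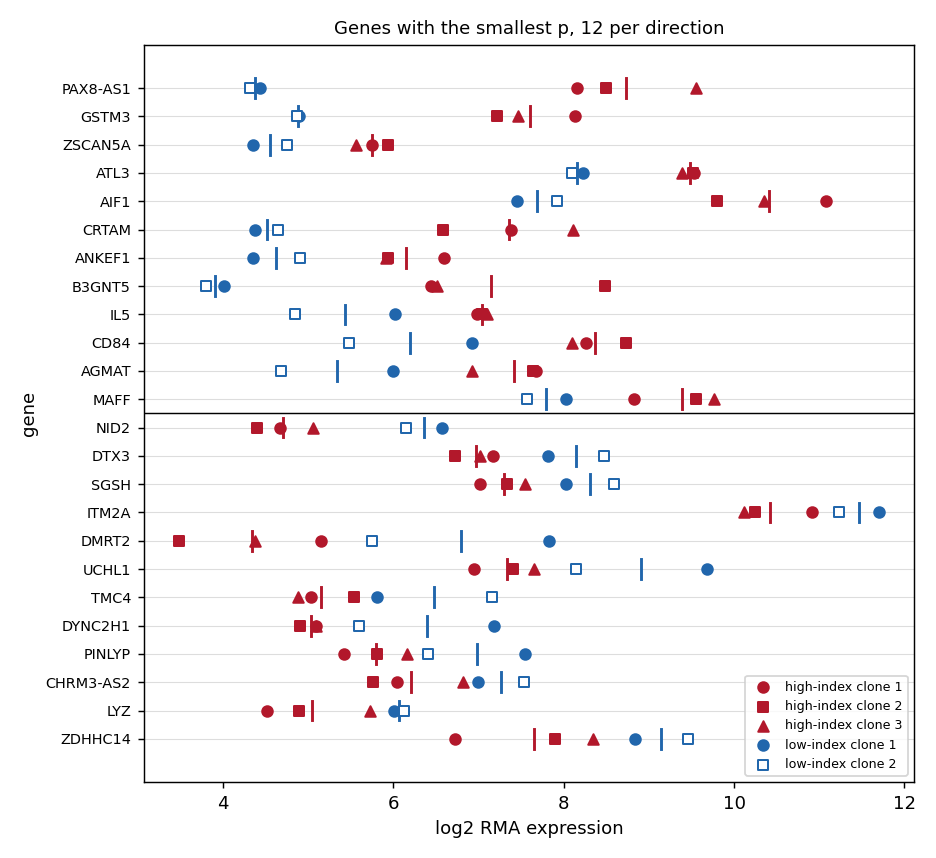
Log2 expression of the 24 genes chosen by p, fold and lack of overlap in each clone (high-index red, low-index blue), with vertical bars at the group means; the upper 12 genes had the higher mean in high-index clones and the lower 12 in low-index clones. PAX8-AS1 lies between 8.15 and 9.56 in the 3 high-index clones and at 4.44 and 4.32 in the low-index clones.

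Over the 11804 tested genes, 138 had an unadjusted limma p under 0.05 (84 with the higher and 54 with the lower mean in high-index clones), where chance alone would give 590.2. At an unadjusted p under 0.01 and a difference of at least 2-fold, there were 14 genes, 13 higher and 1 lower, and with each array centred on its median there were 21, of which 15 were higher and 6 lower. An ordinary least squares fit without moderation also called 0 genes, with 154 at an unadjusted p under 0.05. A difference of at least 2-fold was seen for 509 genes, 350 with the higher and 159 with the lower mean in high-index clones. The groups did not overlap for 1196 tested genes, or 10.13%. Chance would give 20% without tied values, and less here, because ties between clones count as overlap. The count of 14 changed with the clones included. It was 12 (9 higher, 3 lower) without high-index clone 1 and rose when either low-index clone was left out. Leaving out a low-index clone sets 3 clones against a lone clone assumed to vary like the others.

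The cytokine genes that name the index overlapped between the groups. IFNG, which encodes interferon-gamma, lay at 8.76 ± 1.63 (SD, n = 3) in high-index and 7.82 ± 4.49 (SD, n = 2) in low-index clones, and low-index clone 1 held the highest and low-index clone 2 the lowest value, 4.65. The high-index clones lay between them, at 8.70, 7.17 and 10.42. IL2 was dim in the resting clones, at 3.08 in each high-index clone and at 3.30 and 2.93 in the low-index clones, and was not tested. TNF and LTA, cytokine genes of the tumour necrosis factor family, differed by 0.68 (SE 0.57) and 1.05 (SE 0.80), each with overlap. The list of type 1 cytokine genes had 16 measured and 13 tested members, with a median log2 difference of 0.18, 10 members with the higher mean in high-index clones and a camera adjusted p of 0.923. Of its members 0 passed over all genes and 0 adjusted over the list alone. The median turned to -0.31 without low-index clone 2.

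Of the type 2 and type 17 cytokine genes, IL5 and IL13 lay higher in all 3 high-index clones than in both low-index clones. IL13, a cytokine of allergic responses, was at 8.26 ± 0.66 (SD, n = 3) against 6.46 ± 1.31 (SD, n = 2), a difference of 1.81 (SE 0.70) with a limma adjusted p of 0.771. The list had 21 measured and 12 tested members, 6 with the higher and 6 with the lower mean, and its median difference of 0.07 turned negative when arrays were centred (-0.08). No member passed over all genes or adjusted over the list alone (0 and 0), and the camera adjusted p was 0.709.

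The genes that mark memory-like or effector-like CD8+ T cells differed little between the groups or varied widely within them. CD27, a costimulatory receptor of memory cells, lay higher in each high-index than in each low-index clone (9.32 ± 0.62, SD, n = 3, against 8.69 ± 0.14, SD, n = 2), a difference of 0.64 (SE 0.42). The differences were -0.38 (SE 0.22) for IL7R, the interleukin-7 receptor, 0.54 (SE 0.77) for CCR7, which guides cells to lymph nodes, and -0.85 (SE 1.25) for LEF1, a transcription factor of naive and memory cells, all with overlap. CD28, the main costimulatory receptor, was dim at 3.97 ± 0.58 (SD, n = 3) and 4.05 ± 0.21 (SD, n = 2) and was not tested. KLRG1, a receptor of late effector cells, had a mean 6.04-fold higher in high-index clones, yet lay at 9.89, 6.19 and 9.86 in them and at 6.90 and 5.21 in the low-index clones. All clones had high levels of PRF1 (perforin) and GZMB (granzyme B), each with a difference of -0.34 (SE 0.23 and 0.41), and the effector transcription factors TBX21 and EOMES differed by -0.35 (SE 0.25) and -0.31 (SE 0.99). CD8A and CD8B, the chains of the CD8 co-receptor, differed by -0.12 (SE 0.20) and 0.65 (SE 0.49). The smallest limma adjusted p among these genes was 0.771.

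The preset lists for these states had no member past the threshold over all genes and none passed the list test. The memory list had 27 measured and 24 tested members, 13 with the higher mean in high-index clones, a median difference of 0.21 and a camera adjusted p of 0.923. That median turned to -0.22 without high-index clone 2. It was -0.069 with the mean of a gene's probe sets and -0.056 with the probe set of largest variance. The members of the memory list with the smallest p included, apart from AIF1, PECAM1, an adhesion molecule of naive T cells, at 2.56 (SE 1.20), and NELL2, at 1.25 (SE 0.55). PECAM1 overlapped between the groups: it lay at 6.57 and 10.37 in low-index clones 1 and 2, against 11.52, 11.23 and 10.34 in the high-index clones. The cytotoxic granule list (20 measured, all tested) had a median of 0.06, which turned to -0.09 with arrays centred, and an adjusted p of 0.880, and the effector differentiation list (18 measured, 15 tested) had a median of -0.02 and an adjusted p of 0.682. The CD8 T cell identity list (18 measured, all tested) had a median of 0.08, which turned to -0.08 with arrays centred, and an adjusted p of 0.923. Adjusted over the list alone, each of the 4 lists had 0 members under 0.05.

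Among surface receptors, CD200R1, an inhibitory receptor, and CD5, which dampens T cell receptor signals, lay higher in every high-index than in every low-index clone, by 1.42 (SE 0.43) and 0.81 (SE 0.36). TIGIT, an inhibitory receptor, differed by 1.97 (SE 0.90) and LAG3, another, by -0.72 (SE 0.39), both with overlap. Of the inhibitory receptor list, 20 members were measured and 19 tested, 9 with the higher and 10 with the lower mean. Its median was -0.03 and its mean 0.23, and the camera adjusted p was 0.984. Of the costimulatory receptor list, 17 were measured and 15 tested, 13 with the higher mean, with a median of 0.55 and an adjusted p of 0.682. TNFRSF8 (CD30) differed by 0.88 (SE 0.37) and ICOS, a receptor of the CD28 family, by -0.73 (SE 0.35), each without overlap. Both lists had 0 members past the threshold over all genes and 0 adjusted over the list alone, and the costimulatory median turned to -0.19 without low-index clone 2.

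Of the NK receptor list, 17 members were measured and 13 tested, 11 with the higher mean in high-index clones. Adjusted over the list alone, with no correction for the number of lists, 1 member passed: CRTAM, with a limma adjusted p of 0.0312. Over all genes 0 passed. KLRD1 (CD94) differed by 1.11 (SE 0.73) and FCER1G, a signalling adaptor, by -1.57 (SE 0.87). The median difference of 0.54 had a camera adjusted p of 0.410 and turned to -0.23 without low-index clone 2. Without high-index clone 2 it was 0.90 and passed at camera's preset correlation of 0.01, with an adjusted p of 0.00275 in a range of 0.00275 to 0.997 over the alternatives that change 1 choice. The correlation estimated between its members was 0.66 in the 5 clones and 0.29 without high-index clone 2, and with it the adjusted p was 0.988 and 0.959, so the pass was lost. The common gamma chain cytokine signalling list (21 measured, all tested) had a median of -0.14 and an adjusted p of 0.169; without high-index clone 2 it passed at -0.18, with an adjusted p of 0.0393 in a range of 0.0393 to 0.988, and with an estimated correlation it did not (0.959). The chemokine receptor and homing list (22 measured, 18 tested) had a median of 0.01 and an adjusted p of 0.732, and CCR2, a receptor for monocyte chemoattractants, differed by 1.18 (SE 0.53). Without low-index clone 2 the median of that list was -0.33 and it passed, with an adjusted p of 0.00879, a comparison of 3 clones with a lone clone assumed to vary like the others; with an estimated correlation it did not pass (0.791). Over the alternatives that change 1 choice its adjusted p ran from 0.00879 to 0.988, and in the full set scaling turned the median to -0.07 (quantile) or -0.15 (centred). Neither list had a member past the threshold over all genes (0) or adjusted over the list alone (0).

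MHC class II genes, which human T cells express once activated, varied more between the low-index clones than between the groups. HLA-DRA, the alpha chain of HLA-DR, lay at 12.20 in low-index clone 1 and 5.79 in low-index clone 2, against 11.71, 8.60 and 10.21 in the high-index clones. CD38, a surface enzyme of activated T cells, differed by 1.20 (SE 0.95). Of the list, 11 members were measured and 10 tested, 6 with the higher mean, with 0 past the threshold over all genes and 0 adjusted over the list alone. The median of 0.23 had a camera adjusted p of 0.880 and turned to -1.25 without low-index clone 2, with an adjusted p of 0.0187, again 3 clones against 1, and 0.791 with an estimated correlation; over the alternatives that change 1 choice it ran from 0.0187 to 0.988.

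Cell cycle, mitochondrial respiration and cholesterol synthesis genes had higher means in high-index clones almost throughout, and low-index clone 2 had the lowest level of each list. The cell cycle list had 32 measured and tested members, of which 31 had the higher mean, with a median log2 difference of 0.93. CCNB1 and CCNB2, the cyclins that drive entry into mitosis, differed by 1.73 (SE 1.09) and 1.63 (SE 1.06), and CDC6, which licenses DNA replication, by 1.47 (SE 0.93). Of the mitochondrial respiration list, 23 members were measured and 22 tested, 21 with the higher mean and a median of 0.44. TFAM, which maintains mitochondrial DNA, differed by 0.96 (SE 0.54) and the ATP synthase subunit genes ATP5F1A and ATP5F1B by 0.52 (SE 0.31) and 0.47 (SE 0.26). Of the cholesterol synthesis list, 18 members were measured and tested, 17 with the higher mean and a median of 0.73. HMGCS1, an early enzyme of the pathway, differed by 1.33 (SE 0.68), INSIG1, a sterol sensor, by 0.96 (SE 0.51), and SCD, a fatty acid desaturase, by 0.85 (SE 0.39). With camera's preset correlation the adjusted p was 5.12e-04, 0.00282 and 0.0058 for the 3 lists, and they were the only lists of 25 to pass. With an estimated correlation each had an adjusted p = 0.988, and with fry each had an adjusted p = 0.982, so 0 lists passed with either. No member of the 3 lists passed over all genes or adjusted over the list alone (0 in each).

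The 3 calls rested on low-index clone 2. The median level of the cell cycle list was 9.96, 9.19 and 8.33 in the high-index clones, 9.14 in low-index clone 1 and 7.18 in low-index clone 2, and that of the cholesterol list was 9.31, 8.97 and 8.91 against 8.94 and 7.55. Without low-index clone 2 the median differences were 0.10 for cell cycle, 0.00 for mitochondrial respiration and 0.06 for cholesterol synthesis, with camera adjusted p of 0.541, 0.913 and 0.770. Without low-index clone 1 the median differences were 1.73, 0.91 and 1.23. Leaving out either low-index clone sets 3 clones against a lone clone assumed to vary like the others. Without high-index clone 1 the cell cycle list had a median of 0.45 and an adjusted p of 0.120.

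**Figure D2:**
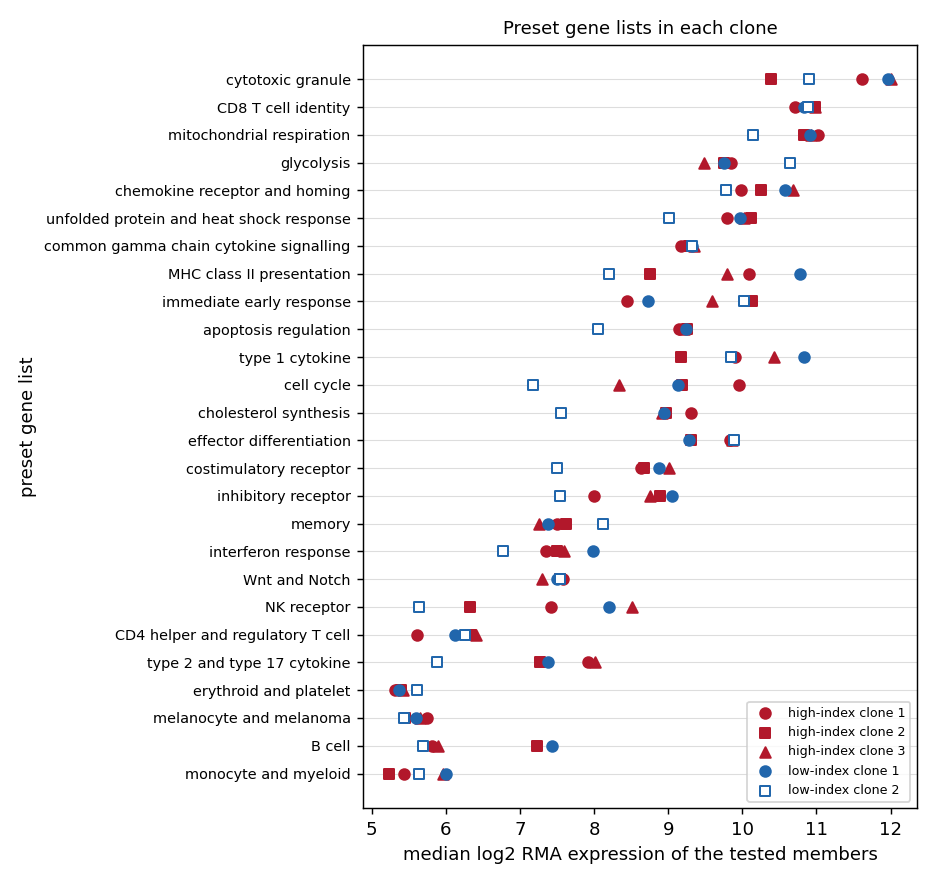
Median log2 expression of the tested members of each preset list in each clone, high-index red and low-index blue. For the cell cycle, mitochondrial respiration and cholesterol synthesis lists, low-index clone 2 (open square) lies below the other 4 clones, with low-index clone 1 among the high-index clones.

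None of the other process lists passed in the 5 clones. Glycolysis genes (23 measured, all tested) had a median of -0.07 and an adjusted p of 0.163. GPI, which acts early in glycolysis, lay at 12.58 in low-index clone 2 against 10.67 to 11.15 in the other clones, and HK2, a hexokinase, differed by 0.61 (SE 0.25). The list lay highest in low-index clone 2 (10.64, against 9.48 to 9.84 in the other clones). Without low-index clone 1 it passed at a median of -0.29 (adjusted p 9.32e-04), and without low-index clone 2 it passed at a median of 0.07 (adjusted p 0.0187). With array weights, with the stricter filter on dim genes and without high-index clone 1 it passed at a negative median (adjusted p 0.0287, 0.0149 and 0.0330), and over the alternatives that change 1 choice the adjusted p ran from 9.32e-04 to 0.988. These 5 passes were at camera's preset correlation of 0.01, and each was lost with the correlation estimated under the same alternative (adjusted p of 0.791 to 0.994). In the 5 clones the estimated correlation was 0.37, with an adjusted p of 0.988, and fry gave 0.982. Interferon response genes (24 measured, 20 tested) had a median of 0.19 and an adjusted p of 0.984, with MX1, an antiviral GTPase, at 1.15 (SE 0.51) and XAF1, a pro-apoptotic interferon-induced gene, at -0.60 (SE 0.26). Without low-index clone 2 the median was -0.26 and passed, with an adjusted p of 0.0143 in a range of 0.0143 to 0.997 over the alternatives that change 1 choice, and with an estimated correlation it did not (0.791). Apoptosis genes (22 measured, all tested) had a median of 0.21 and an adjusted p of 0.732. That median was -0.096 without low-index clone 2 and 0.51 without low-index clone 1. BMF, a pro-apoptotic member of the BCL2 family, differed by -0.88 (SE 0.16) without overlap, with a limma adjusted p of 0.0751 over the list alone. BAX, another pro-apoptotic member, differed by 1.03 (SE 0.53), and XIAP, a caspase inhibitor, by 0.85 (SE 0.43). Each of these lists had 0 members past the threshold over all genes and 0 adjusted over the list alone.

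The Wnt and Notch list (27 measured, 20 tested) had a median of -0.05 and an adjusted p of 0.682, and the unfolded protein and heat shock response list (21 measured, 20 tested) a median of 0.24 and an adjusted p of 0.635. The immediate early list (22 measured, 20 tested), genes induced within minutes by stimulation or by handling of cells, had a median of -0.22 and an adjusted p of 0.389, with ATF3 at 1.22 (SE 0.99) and NR4A2 at -0.89 (SE 0.83). Its level over all measured members was 9.66 in high-index clone 2 and 9.92 in low-index clone 2, against 7.95 to 8.93 in the other clones. Without high-index clone 2 that list passed at a median of -0.43, with an adjusted p of 0.00275 in a range of 0.00275 to 0.988 over the alternatives that change 1 choice, and with an estimated correlation it did not (0.959). Each of these 3 lists had 0 members past the threshold over all genes and 0 adjusted over the list alone.

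Markers of other cells that a culture could hold had median levels under the 40th percentile of all genes for 4 of the 5 lists, and about the middle of all genes for the CD4 T cell list. The median level of the measured members stood at the 30.7th percentile of all genes for B cells (16 measured, 5 tested), at 23.4 for monocytes and myeloid cells (18 measured, 4 tested), at 32.7 for melanocytes and melanoma (13 measured, 5 tested), at 39.1 for erythroid cells and platelets (12 measured, 6 tested) and at 49.4 for CD4 helper and regulatory T cells (11 measured, 8 tested). The most abundant member of the myeloid list was AIF1, at a mean of 9.32 over the 5 clones, which is also in the memory list. Its limma adjusted p was 0.00871 over the myeloid list alone and 0.0523 over the memory list alone. LYZ, another member, had the lower mean in high-index clones. In the myeloid list 1 member passed adjusted over the list alone, that is over 4 tested members and with no correction for the number of lists. The other 4 lists had 0 members past the threshold adjusted over the list alone, and all 5 had 0 over all genes. The median differences were -0.08 for B cells, -0.03 for CD4 T cells, 0.13 for melanocytes (-0.02 with arrays centred) and -0.01 for erythroid cells, with camera adjusted p of 0.389, 0.880, 0.982 and 0.690. The myeloid list had too few tested members for the list test.

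Of 7 measures of the array's control probe sets, 3 separated the groups and 4 overlapped. The hybridization spike-ins, bacterial and phage transcripts added to each labelled sample in fixed amounts, averaged 10.43 ± 0.35 (SD, n = 3) in the high-index and 11.30 ± 0.09 (SD, n = 2) in the low-index arrays, a log2 difference of -0.88. The 3′ minus 5′ log2 difference of ACTB (beta-actin), a measure of how far along the transcript the labelling reached, averaged 0.33 ± 0.20 (SD, n = 3) against 0.73 ± 0.14 (SD, n = 2), a difference of -0.40. That of GAPDH was also smaller in the high-index arrays, with a difference of -0.21. These 3 measures separated the groups without overlap, which gives p = 0.2 in a two-sided exact permutation test, the smallest p that 3 against 2 samples allow. The 4 that overlapped were the poly-A spike-ins, with a difference of -0.68 and p = 0.4 in the same exact test, the Trp probe sets (0.08, p = 0.6), the ribosomal RNA probe sets (-0.46, p = 0.6) and the Alu probe set (-0.13, p = 0.4). Array or labelling batches are not given in the sources used here, so no value within a batch can be had.

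**Figure D3:**
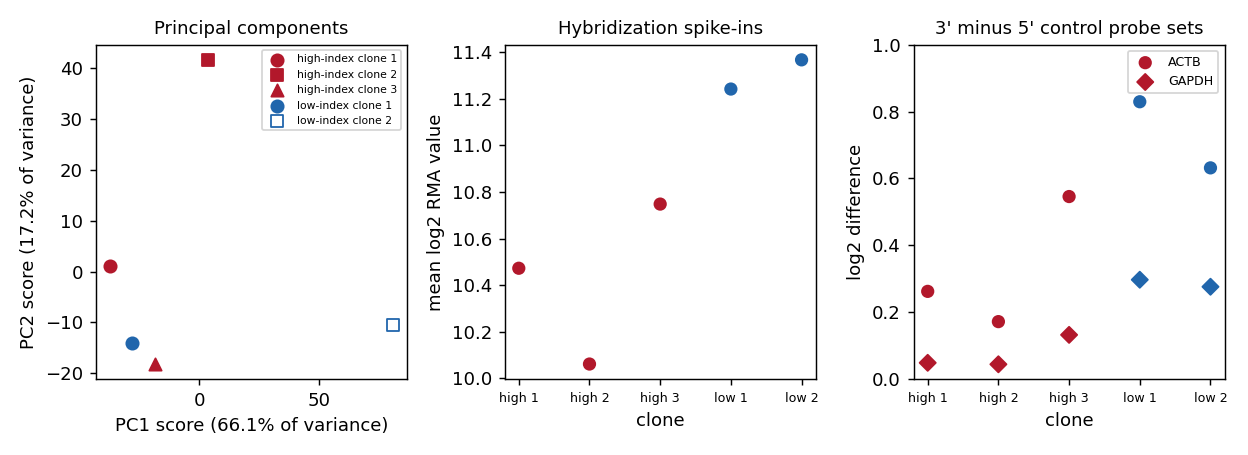
Left, scores of the 5 clones on the first (66.1% of the variance) and second (17.2%) principal components of the tested genes, with high-index clones in red and low-index clones in blue. Middle and right, for each clone, the mean log2 value of the hybridization spike-ins and the 3′ minus 5′ log2 difference of the ACTB and GAPDH control probe sets. Low-index clone 2 lies alone at the right of the component scores, and both low-index clones lie above all 3 high-index clones in the spike-in and 3′ minus 5′ values.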

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

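The tests in this part were chosen only after the results were seen. The control probe sets of the array, which enter no comparison of genes, separated the groups in 3 of 7 measures and overlapped in the other 4. The hybridization spike-ins differed by -0.88 (high-index minus low-index, log2), the ACTB 3′ minus 5′ difference by -0.40 and the GAPDH 3′ minus 5′ difference by -0.21, each without overlap and each with p = 0.2 in a two-sided exact permutation test, the smallest p that 3 against 2 allows. An array or labelling batch that moved many genes cannot be told apart. Of the tested genes, 10.13% had no overlap between the groups. Chance would give 20% without tied values, and less with the ties present here. The share ran from 6.46% to 37.24% over the other splits of the 5 clones into 3 and 2. A difference in RNA amount, labelling or array batch that shows mainly in the controls cannot be told apart from the index groups either, because the value of -0.88 comes from arrays whose batch is not given in the sources used here. A difference in the cells that goes with the index itself was not tested and stays open.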

How the results depend on the processing

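All alternatives were planned, except that the estimated correlation under each other alternative was chosen after seeing the data. For the changes below the cause was not tested unless fewer samples or genes show it. Limma called 0 genes at an adjusted p under 0.05 under every alternative run, at an adjusted p under 0.1 and with ordinary least squares too; 138 genes had an unadjusted p under 0.05 with limma as reported and 154 with ordinary least squares. The 24 genes chosen by p kept their direction under every alternative that keeps all clones; leaving out a clone cannot turn them, since they were chosen for having no overlap. Of all 76 genes compared, 9 reversed when some clone was left out, and the smallest adjusted p among the 76 ran from 0.06 (without low-index clone 1) to 0.99 (array weights). The count of 14 genes at an unadjusted p under 0.01 and at least 2-fold fell to 5 with array weights, to 9 with no filter on dim genes (8 higher, 1 lower) and to 5 with the filter at the 60th percentile. It ran from 12 (without high-index clone 1) to 1052 (without low-index clone 1) with a clone left out; leaving out a low-index clone sets 3 clones against a lone clone assumed to vary like the others. The 3 list calls held under 10 of the 12 alternatives that keep all clones, with medians of 0.66 to 1.31 (cell cycle), 0.29 to 0.47 (mitochondrial respiration) and 0.46 to 0.86 (cholesterol synthesis). The eBayes settings, without a trend and with a robust prior, are among the 10. They could not change a list call, since camera does not use that fit. With camera's estimated correlation 0 lists passed and with fry 0 lists passed. With a clone left out 3 (without high-index clone 1 or 3) to 6 lists (without high-index clone 2) passed at the preset correlation. With the estimated correlation 0 lists passed under each of 15 other alternatives, each clone left out and the same eBayes settings among them. That correlation was estimated from the residuals of the same few clones. Neither it nor fry was shown on simulated data to recover a shifted list. A pass lost with them therefore leaves open whether the list differs. The correlation of the low-index clones, 0.861, was 0.946 with no filter, 0.762 with the filter at the 60th percentile, 0.880 with the mean of a gene's probe sets and 0.803 with the probe set of largest variance.

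With the clone number as a replicate block, 55 genes (38 higher, 17 lower) had an unadjusted p under 0.01 and at least 2-fold, 0 genes and the same number of lists (3) passed, and the medians of the cytotoxic granule (-0.067), chemokine receptor (-0.036) and CD8 T cell identity lists (-0.033) and the difference of CD28 (0.033) reversed. Whether same-numbered clones share a patient is not given in the sources used here. The deviations of high-index clones 1 and 2 from their group mean correlated across genes at 0.42 and 0.42 with those of the low-index clones of the same number. The deviations of the low-index clones from their mean mirror each other, and only 2 numbers are shared, so the block was not taken as a pairing, which leaves a shared patient open.

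Small list medians reversed under other settings, none of them past the threshold. With array weights the inhibitory receptor median was 0.021. With no filter, those of the effector differentiation, type 2 and type 17 cytokine and melanocyte lists were 0.043, -0.0025 and -0.026, and with the filter at the 60th percentile that of type 2 and type 17 was -0.012. With the mean of a gene's probe sets the memory, cytotoxic granule, inhibitory receptor and CD8 identity medians were -0.069, -0.019, 0.0080 and -0.0030, and CD28 differed by 0.11; with the probe set of largest variance the memory, cytotoxic granule, inhibitory receptor and CD4 T cell medians were -0.056, -0.022, 0.044 and 0.013. Quantile normalization gave -0.045, -0.068 and -0.050 for cytotoxic granule, chemokine receptor and CD8 identity. Centring gave -0.090, -0.083, -0.15, -0.077 and -0.021 for cytotoxic granule, type 2 and type 17, chemokine receptor, CD8 identity and melanocyte lists.

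With a clone left out, 11 list medians reversed without low-index clone 2. Of the medians that reversed without some clone, those lowest without low-index clone 2 and highest without low-index clone 1 ran from -0.20 to 0.29 (cytotoxic granule), -0.23 to 0.97 (NK receptor), -0.056 to 0.36 (inhibitory receptor, which reversed without low-index clone 1), -0.19 to 0.85 (costimulatory), -0.31 to 0.71 (type 1 cytokine), -0.33 to 0.43 (chemokine receptor), -0.096 to 0.51 (apoptosis), -0.26 to 0.74 (interferon) and -1.25 to 1.37 (MHC class II). The other ranges were -0.22 to 0.39 (memory), -0.16 to 0.021 (effector), -0.18 to 0.063 (common gamma chain), -0.033 to 0.083 (CD8 identity), -0.11 to 0.028 (Wnt and Notch), -0.29 to 0.070 (glycolysis), -0.43 to 0.21 (immediate early), -0.053 to 0.15 (CD4 T cell) and -0.036 to 0.015 (erythroid). Gene differences ran from -0.22 to 0.14 (IL2), -2.24 to 4.12 (IFNG), -0.41 to 0.14 (CD28), -0.60 to 1.68 (CCR7), -2.81 to 1.11 (LEF1), -1.14 to 0.46 (EOMES), -0.28 to 0.049 (CD8A), -0.041 to 1.35 (CD8B) and -2.03 to 4.39 (HLA-DRA). Genes near the dim level, IL2 and CD28 among them, have values that signal over background limits.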

Other observations

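Of the tests in this part, only that of the 2 growth lists was written down before its result was seen. It was written to explain why low-index clone 2 stood apart, so after that distance was known. The other tests, and the comparison with genes of like level, were chosen after their results were seen. Ribosome biogenesis and nucleotide synthesis genes, which serve cell growth, lay lowest in low-index clone 2: the median level of the 26 tested members was 8.77, 8.52 and 8.09 in high-index clones 1, 2 and 3, 8.45 in low-index clone 1 and 7.12 in low-index clone 2. Genes linked to quiescence (19 tested) lay at 9.48 in low-index clone 2, against 8.96 in low-index clone 1, 9.01 in high-index clones 1 and 3, and a level between these last values in high-index clone 2. Neither list had a member past the threshold between the index groups (0 and 0). High-index clone 2 and low-index clone 2 shared the highest levels of the immediate early list and also of the ribosomal RNA control probe sets, at 10.23 and 10.81 against 9.02 to 9.27 in the other clones.

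Low-index clone 2 stood apart from the other 4 clones. The index group as the whole source of its distance from the high-index clones is argued against on 1790 genes where it lay at least 2-fold outside those clones, chosen without low-index clone 1: the median share of that shift in low-index clone 1 was -0.0126 (quartiles -0.11 and 0.07), and 0.20 at most in a high-index clone held out in the same way. A part that goes with the index was not tested and stays open. RNA degradation as the whole source is argued against by 3′ minus 5′ differences of 0.63 for ACTB and 0.28 for GAPDH. Both lay below those of low-index clone 1 (0.83 and 0.30), which did not stand apart. Both lay above those of every high-index clone (at most 0.55 and 0.13), so a part played by RNA quality stays open. B, myeloid, melanocyte or erythroid cells as much of the culture are argued against, since the most that any of their 59 measured markers lay above the highest other clone was 0.56 log2, but a small share of other cells stays open: 0 of the 4 lists over all members, and 1 of 4 over tested members (erythroid), lay above the other clones by more than their range. For a weaker labelled sample, 60.9% of the glycolysis genes were highest there, against 24.4% of all tested genes. Glycolysis was picked after that list was seen to lie highest there. It was the only list of abundant genes above the other clones, so it cannot decide. Of 13 lists of abundant genes, 6 lay inside or above the range of the other clones and 7 below it. The hybridization spike-ins were highest (11.37, little above the 11.24 of low-index clone 1). The poly-A spike-ins were not (7.58, below 7.96 in low-index clone 1 and 7.60 in high-index clone 3). The array's SD was the smallest (2.23 against 2.32 to 2.36), and the median deviation from the other clones reached -0.65 among abundant genes. As the whole cause or as part of it, a weaker labelled sample cannot be told apart. A candidate explanation, as a hypothesis beside it, is a lower growth state of that clone when RNA was taken: 84.6% of the ribosome biogenesis and nucleotide synthesis genes were lowest there, against 56.1% of genes of like level, while 31.6% of the quiescence genes were highest there, against 17.4% of genes of like level, which leaves that test open. The glycolysis genes, 60.9% of them highest in that clone, were not part of the growth test, and whether they go with a lower growth state was not tested. Genes of a list can move together within a clone, so these shares describe that clone and carry no p-value.

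The higher means of the cell cycle, mitochondrial respiration and cholesterol synthesis lists in high-index clones may come from that clone alone, as a hypothesis: without it the largest of the 3 median log2 differences was 0.0994 and none of the 3 lists passed. Correlation between list members, which camera's preset value of 0.01 leaves small, could also account for the calls. The smallest of the 3 estimated correlations was 0.58 and no list passed with them. They come from the residuals of the same few clones, low-index clone 2 among them. Without that clone they were 0.96 for cell cycle, 0.46 for mitochondrial respiration and 0.30 for cholesterol synthesis. The test was not shown to recover a shifted list, so the lost calls cannot decide this. Low-index clone 2 also lay below the other clones for most abundant genes of any kind. Among the 1181 tested genes of highest level, 83.4% were lower there, with a median deviation of -0.61 from the other clones. The 3 lists were not compared with genes of like level. Whether they fell further in that clone than such genes was therefore not tested. No value here ties the 3 lists to the index.

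The 5 clones can be split into 3 and 2 in 10 ways, too few for a share under 0.05. At an unadjusted p under 0.01 and at least 2-fold, the real split gave 14 genes and the highest other split 351; 7 of the 10 splits, the real one included, gave as many as the real one. For the preset lists the real split gave 3 and the highest other split 11, and 9 of the 10 gave as many. The split with 351 genes sets high-index clone 2 and low-index clone 2 against the rest. It joins the clone that stood apart to the clone closest to it (correlation 0.900), so its count points to the structure of the samples that the correlations already show.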
